A study of Penicillium oxalicum with 12 samples.

How the data were processed

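Messenger RNA was sequenced from mycelia of the filamentous fungus Penicillium oxalicum. Per the labels' protocols, cultures grew for 24 h in a mineral medium with 2% glucose and were then moved to the same medium without a carbon source for 4 h, at 30 °C and 200 rpm. mRNA capture was followed by a strand-specific library kit, per the labels' protocols. The 12 libraries form 4 groups of 3: wild type 114-2 (WT), and strains that express a chimeric transcription factor named CXC (gCXC), a variant of the regulator XlnR with the substitution A871V (gXlnRC) or a variant of the regulator AraR with the substitution A731V (gAraRC). The series' design text describes the 3 libraries of a group as biological replicates and WT as the control.

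The authors deposited 1 table of FPKM values (fragments scaled to gene length and to a total for the library), with 9979 genes and a column for each library. The submitters' processing notes name CASAVA 1.8, HISAT2 2.0.0, featureCounts 1.5.0-p1 and DESeq2, without saying what each was used for. The genome build, the annotation, the strand setting of the counting and the denominator of the FPKM values are not given in the sources used here. Without the strand setting, genes that overlap on opposite strands could share counts, and near-identical gene copies could share reads. The table names genes by PDE locus tags and does not pair them with gene names. Of the 9979 tags, 0 matched the reference gene table at hand, which describes another assembly (ASM172317v3), so no gene is named or assigned a function.

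For this reason the functional gene lists and their set tests, the conidiation markers and the check of the regulator genes that had been fixed before the data were examined could not be run. The expression of the engineered factors themselves is therefore not reported, and the labels could not be checked against it. The rule for named genes, fixed before the data were examined, allowed only 2 tags that rose and 2 that fell per comparison when names are missing. They are the called genes with the most extreme log2 changes among those whose libraries did not overlap between the groups and whose mean FPKM was at least 10 in either group.

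Genes with an FPKM of at least 1 in at least 3 libraries were tested (9125 genes). limma 3.58.1 in R 4.3.3 was fitted to log2(FPKM + 1) of all 12 libraries with group means only (8 residual degrees of freedom, trended prior variance). The FPKM values were not rescaled, although their sum was lower in every engineered library than in every WT library, and lowest in gAraRC. Tests were two-sided, with Benjamini-Hochberg adjustment within each comparison, and a gene was called at an adjusted p below 0.05. Counts of genes that also changed at least 2-fold are given beside them. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low FPKM. Lists at a 4-fold threshold, counts of genes that differed from all 3 other groups, read shares and the test of neighbouring locus tags were added after the data were examined. Tables were handled in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

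The FPKM values turned out to be whole multiples of what 1 read is worth, so read numbers, coding lengths in steps of 3 nt and library totals could be inferred. A length was accepted only where all values of a gene came close to whole numbers, and such a length was found for all 9125 tested genes. That 100% of their values above 0 lay within 0.1 of a whole number therefore follows from the search. At 1 wrong length 25.3% did. The totals ranged from 14549534 to 20092360 reads per library, and the summed reads came to at least 99.99% of each total, so totals and read shares refer to reads counted in genes and not to all reads sequenced or mapped. Between 49.2% and 50.7% of the read numbers of a library were even and between 32.5% and 34.2% were divisible by 3. Read numbers wrong by a factor of 2 or 3 would not give this. The length step of 3 nt enters the totals but not the read numbers, so divisibility does not test it. That step was set so that the summed reads match the totals, so their match does not test it either. In simulated tables of 9979 genes, 97.5% of genes were given a length, of which 99.96% were true, and 0 library totals were wrong by over 1%. In smaller simulated tables of 3000 genes, 3 of 5 draws had a wrong total, so the method needs a large table. The recovered reads were used for depth, read shares, replicate noise, a length check and 1 alternative fit (limma voom).

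The limma test was checked on simulated reads for gCXC against WT (8984 genes in that step, with 50 genes changed at each of 4 sizes). It called 54% of genes changed 1.25-fold, 98% of those changed 1.5-fold and 100% of those changed 2-fold or 4-fold. It made 8 false calls, 4.35% of all calls, and 0 calls in a simulated gXlnRC group left unchanged. The simulated reads had a single dispersion (extra variance between replicates) of 0.0037, so genes or groups with more noise were not represented. The changed genes were drawn only from genes above a minimum mean read level in WT, so less abundant genes were left out of the rates. The rates were also not split by abundance, so they cannot be taken to hold for genes with low FPKM or for all 9125 tested genes. Replicate pairs within a group differed by 2.29 to 6.87 times the sampling noise (the median chi-square statistic over genes with at least 50 reads, divided by its value under sampling alone), so no library was counted as a copy of another. The alternatives were other pseudocounts (0.1 and 5), no filter and a stricter filter (mean FPKM of at least 5), median-of-ratios, TPM and quantile scaling, fits with only the libraries compared, without the variance trend, with a robust prior, with library weights or with replicate numbers as a block, and leaving out each library.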

Results

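The data set comprised 12 mRNA libraries from carbon-starved mycelia of Penicillium oxalicum, a fungus that secretes plant cell wall degrading enzymes. The 4 groups of 3 libraries were WT (strain 114-2) and the engineered strains gCXC, gXlnRC and gAraRC. gCXC expresses a chimeric transcription factor, gXlnRC a variant (A871V) of XlnR, known in related fungi as an activator of xylanase genes, and gAraRC a variant (A731V) of AraR, known there as a regulator of genes for arabinose use. The series asked how engineering of transcriptional activators changes the transcriptome. Depth ranged from 14549534 reads counted in genes in gAraRC replicate 2 to 20092360 in gXlnRC replicate 3, as recovered from the FPKM values (read shares below refer to these totals), and the median standard error of a log2 change was 0.09.

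The libraries grouped by strain. The first principal component (47.9% of the variance) set the 3 gAraRC libraries apart from the other 9, the second (25.5%) set gXlnRC apart, and the third (19.0%) separated gCXC from WT. Spearman correlations across genes lay between 0.990 and 0.997 for libraries of the same group and between 0.910 and 0.959 for libraries of different groups. WT and gCXC libraries were the closest different groups (0.956 to 0.959), and WT and gAraRC libraries the most distant (0.910 to 0.920).

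**Figure D1:**
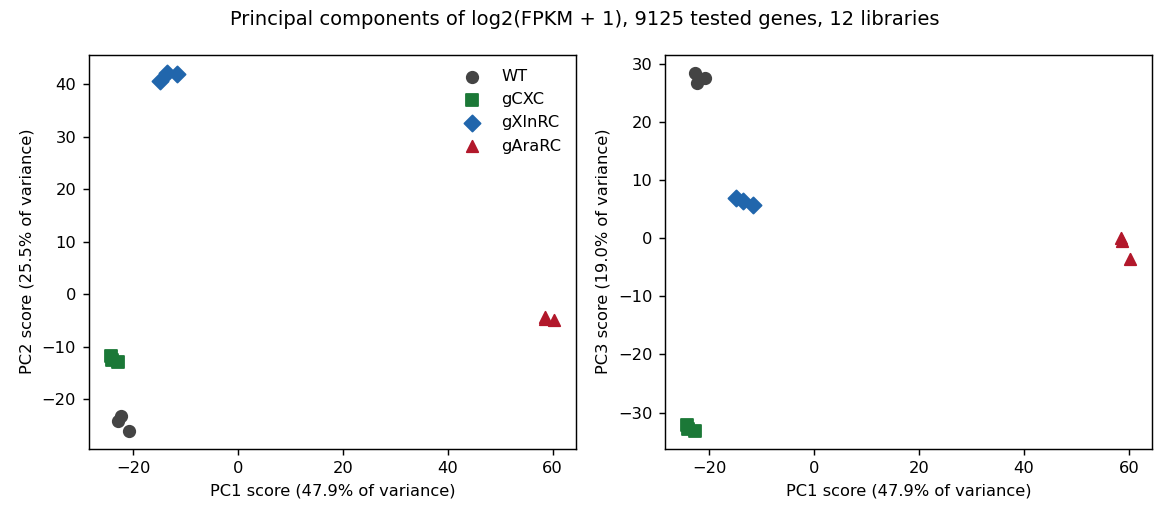
Scores of the 12 libraries on the first 3 principal components of log2(FPKM + 1) over 9125 genes, each point 1 library, colours and symbols giving the strain. The gAraRC libraries lie at 58.5 to 60.3 on the first component, and the other 9 libraries lie below 0.

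In gCXC, the gene PDE_07124 rose from 11.6 ± 0.334 FPKM in WT to 8789 ± 400.2 FPKM (mean ± SD, n = 3 libraries each), a ratio of 758. It took 1.23% of the reads counted in genes in gCXC, against 0.00162% in WT. PDE_02681 rose from 0.460 ± 0.221 to 707 ± 39.4 FPKM. PDE_02123 fell from 212 ± 28.7 to 3.60 ± 0.705 FPKM, and PDE_00021 fell from 1076 ± 65.2 to 26.6 ± 7.10 FPKM. The log2 changes (± SE, limma, Benjamini-Hochberg adjusted p) were 9.45 ± 0.08 for PDE_07124 (adjusted p = 1.54e-15), 8.93 ± 0.15 for PDE_02681 (3.60e-13), -5.54 ± 0.11 for PDE_02123 (2.98e-12) and -5.32 ± 0.16 for PDE_00021 (9.10e-11). PDE_02681 had only 4 to 13 reads per WT library, so the size of its ratio is imprecise.

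The gCXC strain had 4592 called genes of 9125 tested, with 2170 higher and 2422 lower than in WT. This small majority turned under each other scaling, with 2380 higher and 2278 lower by median-of-ratios, 2679 and 2053 by TPM, and 2580 and 2081 by quantile normalization. At least 2-fold changes were fewer and leaned downward, with 186 genes higher and 462 lower (188 and 436, 193 and 409, and 201 and 396 under these scalings). The 186 raised genes held 1.71% ± 0.147 of the reads in WT and 9.77% ± 0.152 in gCXC (SD, n = 3). The 462 lowered genes held 12.9% ± 0.121 in WT and 4.09% ± 0.114 in gCXC. The median log2 change of all tested genes was -0.0026. With a pseudocount of 5, 428 genes changed at least 2-fold instead of 648, 294 of them lower.

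In gXlnRC, PDE_08094 rose from 3.50 ± 0.832 FPKM in WT to 8355 ± 168 FPKM (SD, n = 3), and PDE_08038 rose from 1.86 ± 0.0812 to 2292 ± 99.0 FPKM. PDE_01191 fell from 5127 ± 68.1 to 319 ± 33.1 FPKM. PDE_01194, which held 1.13% of the reads in WT, fell from 16508 ± 863 to 1281 ± 188 FPKM. The log2 changes (± SE, limma, Benjamini-Hochberg adjusted p) were 10.87 ± 0.13 for PDE_08094 (adjusted p = 7.50e-15), 9.65 ± 0.12 for PDE_08038 (1.02e-14), -4.01 ± 0.14 for PDE_01191 (4.41e-10) and -3.70 ± 0.16 for PDE_01194 (3.53e-09). PDE_08094 also rose in both other strains, to 907 ± 72.9 FPKM in gCXC and 172 ± 27.4 FPKM in gAraRC. PDE_08038 did not pass the test in gCXC (2.19 ± 0.302 FPKM) or in gAraRC (1.40 ± 0.487 FPKM).

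The gXlnRC strain had 4983 called genes, with 1746 higher and 3237 lower than in WT. Of the genes that changed at least 2-fold, 306 were higher and 518 lower. The raised genes went from 3.26% ± 0.159 of the reads in WT to 19.2% ± 0.241 in gXlnRC, and the lowered genes from 15.4% ± 0.735 to 4.92% ± 0.175. The median log2 change of tested genes was -0.10 as deposited, and ran from -0.26 in the quintile of shortest coding lengths to 0.07 in that of the longest. The split of the calls depends on how libraries are scaled, and the downward majority at 2-fold shrank under each other scaling. Median-of-ratios scaling gave 2566 genes higher and 2401 lower (363 and 416 at least 2-fold). Quantile normalization gave 2431 higher and 2489 lower (358 and 423), and TPM 2319 higher and 2473 lower (350 and 427).

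In gAraRC, PDE_04016 rose from 0.805 ± 0.278 FPKM in WT to 219.6 ± 52.7 FPKM (SD, n = 3), and PDE_09192 rose from 2.72 ± 0.791 to 307 ± 24.7 FPKM. PDE_01330 fell from 1018 ± 95.0 to 32.5 ± 1.63 FPKM, and PDE_01201 fell from 199 ± 29.3 to 5.70 ± 1.10 FPKM. The log2 changes (± SE, limma, Benjamini-Hochberg adjusted p) were 6.91 ± 0.19 for PDE_04016 (adjusted p = 3.70e-11), 6.39 ± 0.16 for PDE_09192 (2.49e-11), -4.93 ± 0.08 for PDE_01330 (1.32e-12) and -4.90 ± 0.12 for PDE_01201 (2.54e-11). PDE_04016 had 14 to 25 reads per WT library. It also rose in gXlnRC, to 51.8 ± 9.38 FPKM, and stood at 0.129 ± 0.115 FPKM in gCXC, from 1 to 7 reads per library.

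The gAraRC strain differed most from WT by count, with 6944 called genes. As deposited, 1744 were higher and 5200 lower, and of the genes that changed at least 2-fold 553 were higher and 1397 lower. The 553 raised genes held 9.76% ± 0.178 of the reads in WT and 32.4% ± 0.521 in gAraRC. The 1397 lowered genes went from 25.0% ± 0.313 to 7.95% ± 0.111 of the reads. The median log2 change of tested genes was -0.34, and the size of the majority depends on that shift. With median-of-ratios scaling, which removes it, 3109 genes were higher and 3255 lower, and at least 2-fold changes turned to 903 higher and 743 lower. Quantile normalization gave 3035 higher and 3355 lower (865 and 782 at least 2-fold), and TPM gave 2210 higher and 4290 lower (670 and 1061 at least 2-fold). With a pseudocount of 5, 931 genes were at least 2-fold lower.

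**Figure D2:**
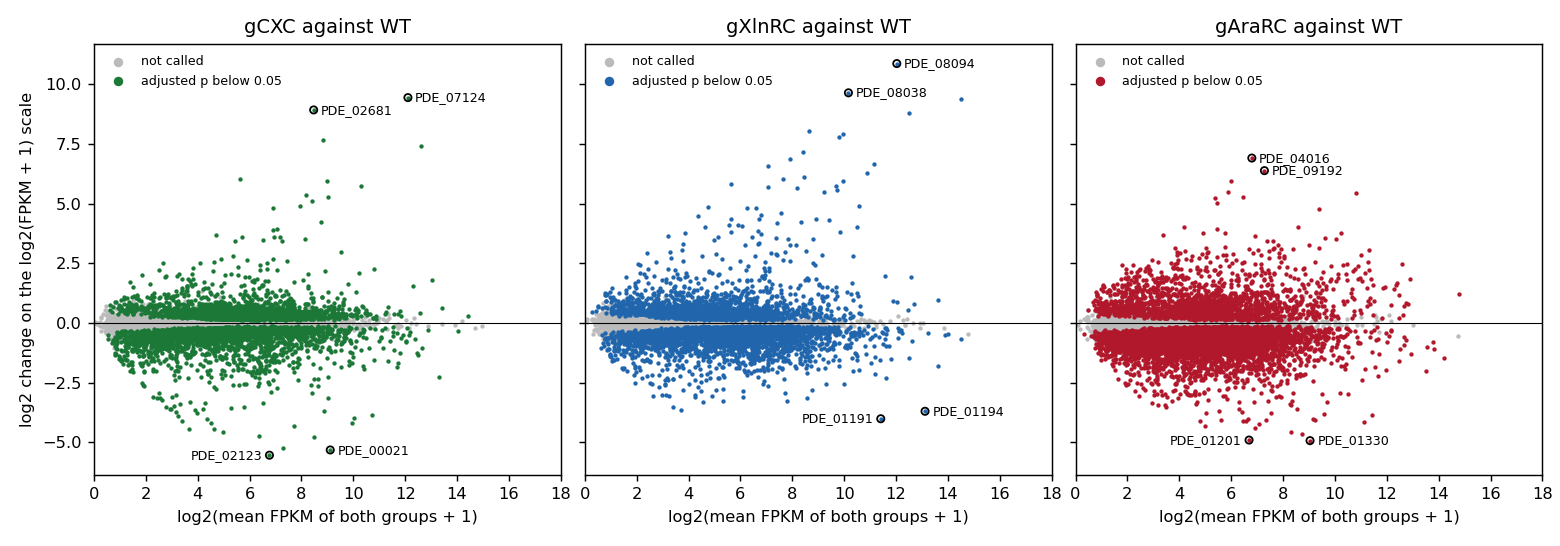
log2 change against log2 mean FPKM for 9125 genes in each engineered strain compared with WT, each point 1 gene, coloured where the limma adjusted p was below 0.05, with the named genes ringed. The cloud of gAraRC is centred below 0 (median -0.34), and those of gCXC (-0.0026) and gXlnRC (-0.10) lie closer to 0.

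**Figure D3:**
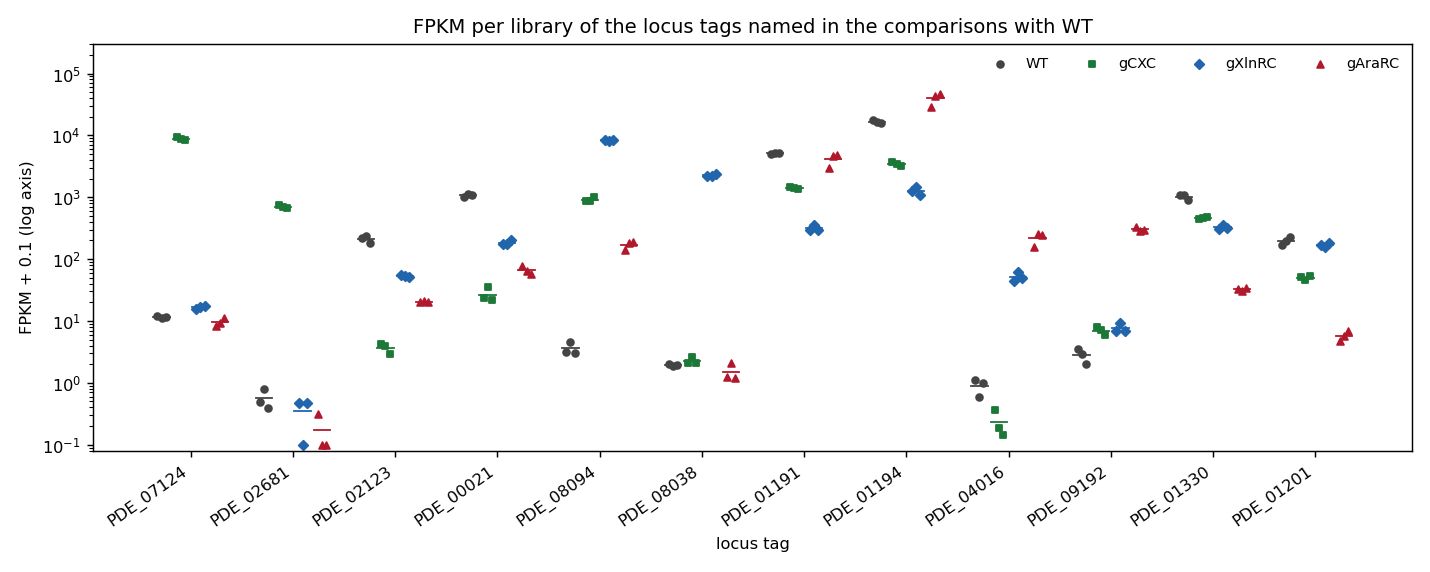
FPKM of the 12 genes named in the comparisons with WT, on a log axis with 0.1 added, each point 1 library and each bar the mean of 3 libraries. PDE_07124 reaches 8789 FPKM in gCXC alone, and PDE_08094 is above WT in all 3 engineered strains.

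The engineered strains were also compared directly. Between gCXC and gXlnRC, PDE_02681 and PDE_07124 were higher in gCXC, with 0.249 ± 0.216 and 16.5 ± 0.998 FPKM in gXlnRC (SD, n = 3). PDE_08038 and PDE_04478 were lower in gCXC. PDE_04478 stood at 46759 ± 1565 FPKM in gXlnRC, 74.3 ± 1.18 in gCXC, 67.9 ± 2.08 in WT and 42.9 ± 1.69 in gAraRC. It took 2.97% of the reads in gXlnRC and was that strain's most abundant gene by FPKM. Its log2 change between gCXC and gXlnRC was -9.28 ± 0.05 (limma, Benjamini-Hochberg adjusted p = 3.30e-18). In this comparison 5349 genes were called, 3297 higher in gCXC and 2052 lower, and 322 were higher and 455 lower at least 2-fold (297 lower with a pseudocount of 5). Median-of-ratios scaling gave 2571 higher and 2532 lower, TPM 2961 and 2181, and quantile normalization 2842 and 2154.

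Between gCXC and gAraRC, PDE_07124 and PDE_02681 were again higher in gCXC. PDE_07124 had 9.51 ± 1.37 FPKM in gAraRC, and PDE_02681 had 0 to 3 reads per gAraRC library, too few for a ratio. PDE_04016 and PDE_04024 were higher in gAraRC, where PDE_04024 had 123 ± 22.2 FPKM, against 0.793 ± 0.207 in gCXC and 1.03 ± 0.484 in WT (SD, n = 3). The log2 change of PDE_04024 was -6.11 ± 0.17 (limma, Benjamini-Hochberg adjusted p = 3.51e-11), and it ran from -7.25 to -4.45 under alternatives. Of 6859 called genes, 4856 were higher in gCXC and 2003 lower, with 1276 higher and 654 lower at least 2-fold. The median log2 change was 0.29, and with median-of-ratios scaling 3166 genes were higher and 3284 lower (700 and 1029 at least 2-fold). Quantile normalization gave 3446 higher and 2996 lower (795 and 884 at least 2-fold), TPM gave 4401 and 2295 (1080 and 734), and with a pseudocount of 5, 402 genes were at least 2-fold lower.

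Between gXlnRC and gAraRC, PDE_04478 and PDE_08038 were higher in gXlnRC, and PDE_09192 and PDE_01194 were higher in gAraRC. PDE_01194 moved in opposite directions in these strains: it stood at 1281 ± 188 FPKM in gXlnRC and 39503 ± 9456 FPKM in gAraRC, on either side of the WT level of 16508 ± 863 (SD, n = 3). Its log2 change against WT was 1.23 ± 0.16 in gAraRC (limma, Benjamini-Hochberg adjusted p = 2.15e-05), and it was the most abundant gene of gAraRC by FPKM. PDE_09192 had 7.61 ± 1.45 FPKM in gXlnRC and 307 ± 24.7 in gAraRC. Of 6617 called genes, 4476 were higher in gXlnRC and 2141 lower, with 1045 higher and 562 lower at least 2-fold. The median log2 change was 0.21, and median-of-ratios scaling gave 3204 higher and 3239 lower (680 and 811 at least 2-fold). Quantile normalization gave 3221 higher and 3219 lower (695 and 784 at least 2-fold), TPM gave 4111 and 2355 (923 and 600), and with a pseudocount of 5, 1029 genes changed at least 2-fold instead of 1607 (666 higher and 363 lower).

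Many genes changed in the same direction in several strains. PDE_08094 was higher, and PDE_02123 and PDE_00021 were lower, in all 3 strains. In gXlnRC and gAraRC, PDE_02123 stood at 53.4 ± 2.18 and 20.5 ± 0.575 FPKM, and PDE_00021 at 182 ± 15.6 and 66.1 ± 11.3 FPKM (SD, n = 3). In all, 35 genes were at least 2-fold higher in all 3 strains and 156 at least 2-fold lower, where independent lists of these sizes would share 0.378 and 4.02. These became 22 and 103 with a pseudocount of 5, and the higher genes 53 with a pseudocount of 0.1 and 58 by limma voom. At least 2-fold lower genes were shared by gCXC and gXlnRC in 238 cases (26.2 for independent lists), by gCXC and gAraRC in 249 (70.7) and by gXlnRC and gAraRC in 300 (79.3). At least 2-fold higher genes were shared in 67 (6.24), 71 (11.3) and 141 (18.5) cases. With a pseudocount of 5, gCXC and gAraRC shared 41 higher and 164 lower genes. The 300 lower genes of gXlnRC and gAraRC became 199 with median-of-ratios scaling, 200 with quantile normalization and 241 with TPM. Opposite changes of at least 2-fold numbered 16, 42 and 38 (26.1, 56.5 and 78.2 for independent lists), and the 16 and 38 became 9 and 25 with a pseudocount of 5.

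The strains were all compared with the same 3 WT libraries. In 100 simulations of unchanged groups against shared controls, the shared lists held at most 1 gene. At most 3 genes were called in any strain there, so near-empty shared lists were fixed in advance and do not judge the observed overlap. The controls could not be split into parts of at least 2 libraries, so part of the excess over independent lists may come from the shared controls. Across genes, which are not independent replicates, the log2 changes correlated at 0.47 (gCXC and gXlnRC), 0.33 (gCXC and gAraRC) and 0.41 (gXlnRC and gAraRC). The simulations without any effect gave a mean of 0.50. Only noise varied there and the controls were shared, which fixes that value, so the observed correlations cannot be judged against it. The covariances were 0.221, 0.183 and 0.262, against a simulated mean of 0.0104 to 0.0105 and at most 0.0122. These values argue against replicate noise in the shared controls as the main source of the covariances. A difference common to all 3 WT libraries was not simulated. With median-of-ratios scaling, 45 genes were at least 2-fold higher and 122 at least 2-fold lower in all 3 strains, and without the size threshold the order turned less one-sided, from 329 higher and 1105 lower to 642 and 712.

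**Figure D4:**
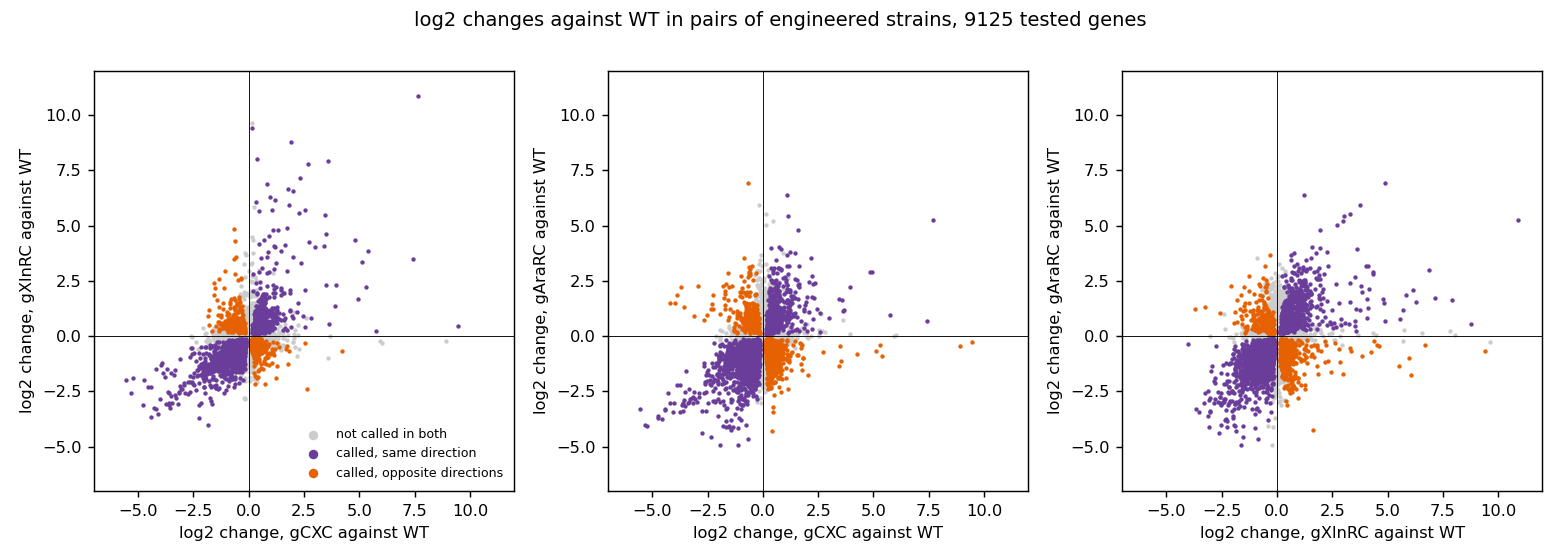
log2 changes against WT in each pair of engineered strains for 9125 genes, each point 1 gene, coloured where both comparisons had a limma adjusted p below 0.05. Genes called in the same direction outnumber those called in opposite directions, for example 779 higher and 1373 lower in both gCXC and gXlnRC against 713 opposite, and the shared WT libraries may contribute to this. The order of higher and lower turned under each other scaling, with 1176 higher and 1096 lower in both by median-of-ratios, 1137 and 1031 by TPM, and 1230 and 1088 by quantile normalization.

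Other genes set 1 strain apart. In direct tests against WT and against both other strains, 64 genes were at least 2-fold higher and 53 at least 2-fold lower in gCXC than in every other group. The numbers were 118 and 48 for gXlnRC and 269 and 552 for gAraRC. With median-of-ratios scaling they were 53 and 69 for gCXC, 121 and 45 for gXlnRC, and 454 and 272 for gAraRC, so the balance in gCXC and gAraRC turns with the scaling. PDE_07124 was among the genes with such a difference in gCXC, as were PDE_08038 and PDE_04478 in gXlnRC and PDE_09192 in gAraRC.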

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

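The limma voom fit on recovered reads was chosen after seeing the data, and the other alternatives before. The named genes were picked for the largest called changes in the same libraries, so keeping their calls says little about other genes. All 24 log2 changes of named genes kept their direction and their call in all 456 values under alternatives (highest adjusted p 7.65e-07, limma). Their sizes moved, for example in genes with few reads in a group: PDE_02681 ran from 7.03 to 10.5 for gCXC against WT, 7.08 to 12.0 against gXlnRC and 7.13 to 13.4 against gAraRC, PDE_04016 from 5.25 to 8.12 for gAraRC against WT and -10.7 to -5.42 for gCXC against gAraRC, and PDE_04024 from -7.25 to -4.45. Of 1284 gene counts (in all and by direction), shared-gene counts and correlations under alternatives, 1236 stayed within 1.5 times the reported count or, for a correlation, within 0.1, and 48 did not. Of these 48, 23 were counts of higher or lower genes. Of 114 median log2 changes under alternatives, 26 moved by more than the spread between replicates. A pseudocount of 5, which shrinks the changes of low genes by construction, lowered the genes changed at least 2-fold to 428 for gCXC against WT and 1029 for gXlnRC against gAraRC (666 higher and 363 lower). It left 294 genes at least 2-fold lower for gCXC against WT, 931 for gAraRC against WT, 297 for gCXC against gXlnRC and 402 for gCXC against gAraRC. It gave 9 and 25 genes with opposite at least 2-fold changes in gCXC and gXlnRC and in gXlnRC and gAraRC, 41 higher and 164 lower in both gCXC and gAraRC, and 22 higher and 103 lower in all 3 strains. A pseudocount of 0.1 gave 53 genes at least 2-fold higher in all 3 strains, and voom 58. Median-of-ratios scaling, which brings the medians of the libraries together by construction, gave 1176, 1081 and 1271 genes higher in both strains of a pair (gCXC and gXlnRC, gCXC and gAraRC, gXlnRC and gAraRC). It gave 1348 lower in both gXlnRC and gAraRC (199 at least 2-fold), and 642 higher and 712 lower in all 3. By direction it gave 3109 higher and 3255 lower for gAraRC against WT (903 and 743 at least 2-fold), 3166 and 3284 for gCXC against gAraRC (700 and 1029), and 3239 lower and 680 at least 2-fold higher for gXlnRC against gAraRC. Quantile normalization gave 1230, 1128 and 1205 higher, 1428 lower, and 659 and 735, and by direction 3035 higher and 3355 lower for gAraRC against WT (865 and 782 at least 2-fold), 795 at least 2-fold higher for gCXC against gAraRC, and 3219 lower and 695 at least 2-fold higher for gXlnRC against gAraRC. TPM gave 494 higher in all 3. With library weights, whose estimation stopped before convergence, 1227 genes were opposite in gCXC and gXlnRC, and the cause was not tested. The weight was 5.89 for WT replicate 2, against 0.446 and 0.485 for WT replicates 1 and 3, so the WT mean rested mostly on 1 library. WT replicates 1 and 3 were also the replicate pair with the highest noise (6.87 times sampling). Leaving out 1 library at a time gave 3930 to 4308 called genes for gCXC against WT, 4401 to 4850 for gXlnRC and 6543 to 6815 for gAraRC. Replicate numbers did not pair the libraries: 3 of 18 same-numbered pairs had deviations correlated above 0.1, and 5 of 12 libraries correlated best with their own number. With replicate number as a block, 4579, 4913 and 6920 genes were called in the 3 comparisons with WT. At this depth and replication, 54% of the smallest simulated changes were called for gCXC against WT, so small changes are missed. Only genes above a minimum read level in WT were changed there, so this rate does not cover less abundant genes. DESeq2 was not run, and limma voom was the only fit made on the recovered reads. The set tests with an estimated correlation and fry were not run because no gene list could be filled.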

Other observations

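The tests of all genes raised at least 2-fold in gAraRC and of neighbouring genes in each strain alone were chosen after the results were seen. Genes that fell strongly in 1 strain were mostly lower in the others too. Of 94 genes at least 4-fold lower in gCXC, 89 were called lower in gXlnRC and 80 in gAraRC, where independent calls would give 33.3 and 53.6. With median-of-ratios scaling the numbers were 89 and 79, against 24.7 and 33.5 for independent calls. Of 50 genes at least 4-fold higher in gCXC, 31 were called higher in gXlnRC and 25 in gAraRC (9.57 and 9.56 for independent calls), and 3 and 11 were called lower. With median-of-ratios scaling, 32 and 33 were higher (14.1 and 17.0 for independent calls). Of 102 such genes in gXlnRC, 65 were higher in gCXC and 61 in gAraRC (24.3 and 19.5), and of 151 in gAraRC, 71 were higher in gCXC and 98 in gXlnRC (35.9 and 28.9). Whether raised and lowered genes differ in sharing was not tested. All of these counts share the same WT libraries. Of the 20 most abundant genes by FPKM, gCXC shared 11 with WT, gXlnRC 12 and gAraRC 10. PDE_06607, chosen after its values were seen, was the most abundant gene in WT (33827 FPKM) and gCXC (30425 FPKM).

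The median log2 change of tested genes in gAraRC was -0.34 as deposited and -0.19 with TPM. TPM makes the summed values of the libraries equal, and the summed FPKM was lower in each gAraRC library than in each WT library. Part of the -0.34 is therefore an offset in these sums, which the unscaled FPKM behind the main calls also carry. The length quintiles cannot show an offset common to all lengths. They argue against a bias that varies with coding length as the whole cause, since their medians all lay at -0.31 or below (-0.38 for the second quintile). Reads taken up by the 151 genes raised at least 4-fold also fall short, since the share they gained would lower all other genes by only -0.12. Reads taken by all 553 genes raised at least 2-fold stay open: their gain alone would lower the rest by -0.42, but genes lowered at least 2-fold gave up reads at the same time, so that the 7175 remaining genes went from 65.2% to 59.6% of the reads, a log2 change of -0.13 in their sum and -0.27 in their median. The 100 genes most abundant in WT went from 31.3% to 36.9% of the reads, with a median log2 change of -0.11. The next 900 went from 34.2% to 31.8% (median -0.45), and the 8125 others from 34.5% to 31.2% (median -0.33). Whether many transcripts fell a little in gAraRC, or a subset of abundant ones rose and displaced them among the reads, cannot be told apart here. The values hold no measure of RNA per cell. No group carried an AraR construct without the substitution, so the variant cannot be told apart from other differences of the strain. The same holds for gXlnRC and gCXC, since no group carried an unsubstituted XlnR construct or a control construct for CXC.

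Raised genes often had neighbouring locus tags, taking tag numbers as the order along the genome, which was not checked. Among 801 genes at least 2-fold higher in at least 1 strain there were 204 pairs with adjacent tags, against at most 99 in 10000 shuffles within deciles of mean FPKM (permutation p = 0.0001, the smallest they can give), which argues against similar abundance of neighbours as the cause. Pairs at tag distances of 2 to 5 numbered 405 against at most 318, which argues against reads shared between adjacent genes as the whole cause, and the longest run was 8 genes. The genes of such a pair can have risen in different strains. Within a strain, adjacent pairs numbered 57 in gXlnRC (shuffled maximum 23) and 142 in gAraRC (53), and pairs at distances of 2 to 5 numbered 99 (63) and 259 (164), which argues against shared reads as the whole cause there too. In gCXC shared reads stay open, with 26 adjacent pairs (shuffled maximum 13) but 18 pairs at distances of 2 to 5 (shuffled mean 13.9, permutation p = 0.1628). Lowered genes were also often neighbours, with 93 adjacent pairs in gCXC (shuffled maximum 40), 104 in gXlnRC (48) and 309 in gAraRC (244), and 206 (124), 219 (145) and 914 (880) at distances of 2 to 5. Reads shared between related tandem copies were not tested.

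Median log2 changes rose with coding length in gXlnRC, from -0.26 in the quintile of shortest genes to 0.07 in that of the longest, and in gCXC from -0.11 to 0.05. The mean coding length weighted by reads was 1459 to 1523 nt in the WT libraries, 1559 to 1606 in gCXC, 1669 to 1854 in gXlnRC and 1700 to 1798 in gAraRC, and whether this reflects RNA or library quality was not tested. For each of the 12 counts of changed genes, 1 of the 10 splits of the 6 libraries compared, the real one, gave as many genes, and the highest of the other splits gave 0. The real counts were 4592, 4983 and 6944 against WT and 5349, 6859 and 6617 between engineered strains, and 648, 824, 1950, 777, 1930 and 1607 at least 2-fold. With 10 splits the share cannot fall under 0.05. Every other split mixed libraries of both strains, which put the strain difference into the spread within its groups. Their count of 0 follows from this mixing and does not judge chance.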
